A study of Homo sapiens with 20 samples.

How the data were processed

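T47D is an established human luminal breast cancer cell line that carries oestrogen and progesterone receptors. Per the labels (the first si-CBX3 0 h library gives no protocol), cells were kept in hormone-depleted and then serum-free medium and treated with 10 nM R5020, a synthetic progestin. RNA-seq libraries from cells given a control siRNA (si-control) or an siRNA against BRG1 (the gene SMARCA4, the ATPase of the SWI/SNF chromatin remodeller), CBX3 (HP1 gamma, a chromatin repressor protein) or FOXA1 (a pioneer transcription factor) were deposited at 0 h and 6 h of hormone, with 2 replicates in each of the 8 groups. A further RNA-seq library without siRNA was deposited for each of 0 h and 6 h, and a list of BRG1 ChIP-seq peaks for each of 0 and 30 min.

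The 16 siRNA files hold counts of fragments per gene that the authors deposited without normalization. Per the file headers they were made with featureCounts 1.4.6-p2, as fragments, in reverse-stranded mode, on GENCODE gene models of hg19. Trimmomatic and STAR are named in the submitters' processing notes, with versions not given in the sources used here. The headers record 1 counting thread for the si-CBX3 and si-FOXA1 files and 8 threads for the si-BRG1 and si-control files, so these sets were counted with separate commands. Totals ranged from 50017255 to 74374857 fragments per library over 57820 genes, and every gene on the mitochondrial chromosome was listed at 0. The 2 files without siRNA hold estimated reads, which need not be whole, and RPKM values per transcript, as deposited by the authors; the quantification tool is not given in the sources used here. Per the file headers and values, the peak lists hold a score per peak, deposited by the authors. The peaks carry MACS names, Bowtie 1.0.0 and HOMER are named in the submitters' processing notes, and the settings of the peak caller and the use of an input are not given in the sources used here. Each list came from 1 library.

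Gene symbols were matched for 39538 of the 57820 genes (68.4%) and for 88.9% of the genes tested; others are named by their identifiers. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 8 groups (18806 genes), library sizes were scaled by TMM, and 1 quasi-likelihood fit with a mean per group gave all comparisons, leaving 8 residual degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg, and a call means an adjusted p below 0.05. The comparisons were the hormone response (6 h against 0 h) under each siRNA, each siRNA against si-control before hormone, the difference of each hormone response from that of si-control, and an average response with siRNA as a covariate (16421 genes). Replicates are separate samples in the labels, which do not say whether they came from separate cultures, so p-values measure only the spread between these samples.

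Gene lists written before the data were examined were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation. They covered progestin- and glucocorticoid-induced genes, oestrogen receptor targets, immediate-early genes, G1/S and G2/M genes, interferon-stimulated genes, NF-kB targets, luminal and basal epithelial markers, mesenchymal, leukocyte and endothelial markers, SWI/SNF subunits, HP1 proteins and co-repressors, linker and core histones, cholesterol and fatty acid synthesis, ATF4 and unfolded-protein stress, p53 targets, hypoxia and glycolysis, TGF-beta and BMP response, and mitochondrially encoded genes (0 measured). Of 220 pairs of list and comparison, 70 passed with the preset correlation and 9 with the estimated one. Genes named were fixed by rule: the siRNA targets, H1-2, PGR, ESR1, FKBP5 and TSC22D3 always; the 10 largest rises and falls of the si-control response, and the 8 of each other comparison named, among called genes with a mean log-CPM of at least 3 whose groups did not overlap; and up to 4 members per list with the lowest p. Of peaks, the 3 with the highest scores in each list and those within 5 kb of a named gene were eligible. CPM values by group are scaled by TMM.

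Transcripts without siRNA were summed per gene. Ratios of 6 h to 0 h are log2 of RPKM plus a pseudocount of 1, and ratios to the siRNA groups use 0.1. With 1 library per time these have no test; list medians are given as percentiles among 10000 random lists matched on expression. Peaks were compared with bedtools 2.31.1 at an overlap of at least 1 bp, and assigned to genes within 5 kb of the 5 prime end, in 1-based hg19 coordinates. Genes with and without a peak were compared by Fisher's exact test and by permutation tests (scipy 1.17.1, 100000 resamples). Shares carry 95% Wilson intervals, which cover counting error only. Comparisons that share si-control were set beside 20 simulations of unchanged groups, drawn around the fitted si-control means. The error of the si-control libraries cancels there, so the simulations do not measure what sharing these libraries adds.

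The procedure was tested on simulated counts with 100 genes changed at each of 2 sizes, among 18806. The changed genes were drawn from those with a mean of at least 1 CPM, so the recovery does not cover genes at lower levels. Each gene had 1 dispersion for all groups. Recovery and false calls therefore do not cover a group with a wider spread, such as si-BRG1 at 6 h. For the si-control response 98% of genes changed by 1 log2 unit and 69% of those changed by 0.5 were recovered, with 11 false calls; for si-BRG1 before hormone 96% and 62%, with 10; for the si-BRG1 difference of response 87% and 27%, with 12. Alternatives were DESeq2 1.42.0, its size factors in edgeR, no or a stricter filter, a 2-fold threshold, only the groups compared, the replicate number as a block, leaving out each library, other gene classes, windows, overlaps and pseudocounts. GC content was not tested, since no genome was used here.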

Results

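Gene expression was measured by RNA-seq in T47D cells under 4 siRNA conditions (si-control, si-BRG1, si-CBX3 and si-FOXA1), at 0 h and 6 h of R5020 with 2 libraries per group. BRG1 binding was recorded as 1 peak list each at 0 and 30 min. By its title the series addresses how progestin represses genes and whether BRG1 and the linker histone H1.2 take part. Values are log2 fold changes with their standard errors (SE) from edgeR, n = 2 per group, unless stated.

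Each siRNA lowered its target before hormone. SMARCA4 (ENSG00000127616.13, chromosome 19, 11071598 to 11176071), which encodes BRG1, was at 5.44 ± 0.647 CPM (SD, n = 2) in si-BRG1 against 71.1 ± 7.69 in si-control, a fall of 13.1-fold. CBX3 (ENSG00000122565.14, chromosome 7, 26240782 to 26252976) fell 38.6-fold and FOXA1 (ENSG00000129514.4, chromosome 14, 38059189 to 38069245) fell 6.42-fold under their own siRNAs. In every library of its own siRNA the target lay below every library of the other siRNAs: SMARCA4 at 2.13 to 5.93 CPM before TMM scaling against 55.8 or more, CBX3 at 2.94 to 6.94 against 230.2 or more, and FOXA1 at 48.9 to 68.7 against 148.8 or more. SMARCA4 rose in the other knockdowns, by 1.34 (SE 0.18) in si-CBX3 and 1.38 (SE 0.18) in si-FOXA1.

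**Figure D1:**
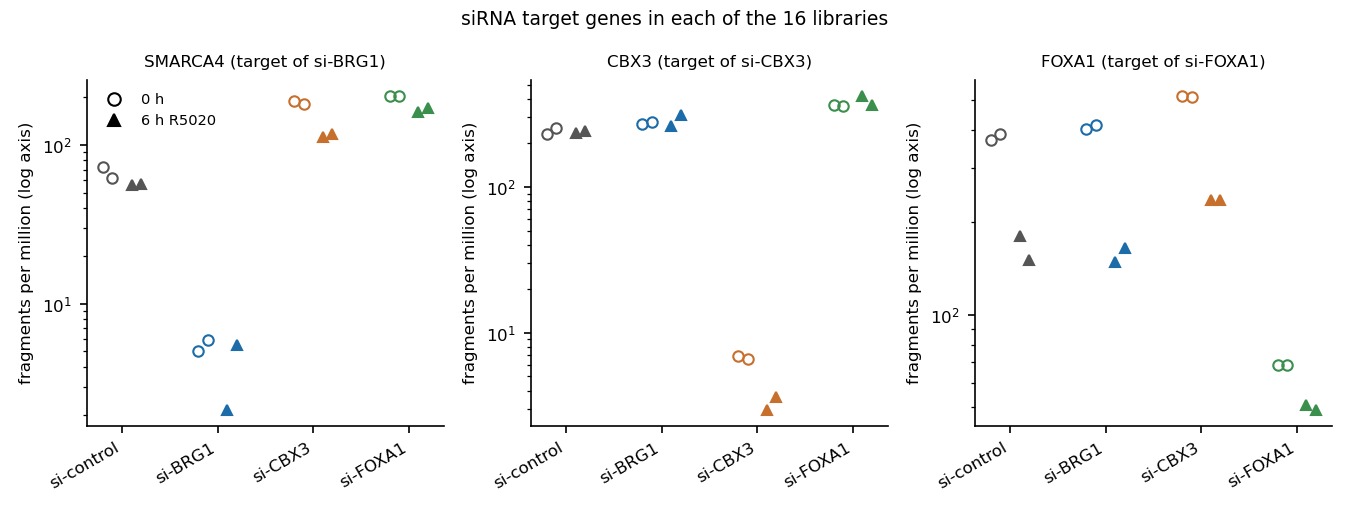
CPM (log axis) of SMARCA4, CBX3 and FOXA1 in each of the 16 libraries, by siRNA; open circles are 0 h and filled triangles 6 h of R5020. Each target is lowest under its own siRNA, and SMARCA4 is higher under si-CBX3 and si-FOXA1 than under si-control.

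R5020 raised canonical targets of the progesterone and glucocorticoid receptors in si-control cells. SGK1 (ENSG00000118515.7), a kinase named for its induction by serum and glucocorticoids, rose 62.4-fold (5.96, SE 0.17), and FKBP5 (ENSG00000096060.10), a co-chaperone of steroid receptors, rose 14.1-fold (3.82, SE 0.07). The zinc finger gene ZBTB7C (5.76), the tissue factor gene F3 (5.60) and the bHLH repressor gene HES2 (5.32) rose most after SGK1, followed by ENSG00000245748 (4.64), ADGRA2 (4.58), KLF15 (4.53), KCNH1 (4.51), CYRIA (4.42) and OTULINL (4.39); without si-control 0 h replicate 1 ADGRA2 was at 5.38. AMIGO2, a cell adhesion gene, fell 12.1-fold (-3.60, SE 0.10), and SOX2 (-3.12), HDAC9 (-2.98), VAV3 (-2.82), LMCD1 (-2.69), PLK2 (-2.51), MECOM (-2.49), SSTR2 (-2.48), LIN28A (-2.48) and IL1R1 (-2.43) were the next largest falls. The receptor genes PGR (-2.42, SE 0.14) and ESR1 (-1.24, SE 0.06) and FOXA1 (-1.12, SE 0.08) fell, and TSC22D3 rose by 1.31.

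Of 25 measured progestin- and glucocorticoid-induced genes 19 rose and 1 fell (20 and 1 adjusted over the list alone), among them DUSP1 (3.16) and STAT5A (3.57), with a list median of 2.02 and adjusted p = 0.00452 with an estimated correlation. This was the only list of the si-control response that passed with an estimated correlation; the next lists passed with the preset correlation alone. Glucose use genes rose, with 12 of 21 hypoxia and glycolysis genes higher and 2 lower (13 and 2 adjusted over the list alone; adjusted p = 0.077 with an estimated correlation), including PFKFB3 (2.83), the glucose transporter gene SLC2A1 (2.05) and HK2 (1.63). DNA replication genes of G1/S rose in 17 of 26 and fell in 1 (19 and 1 adjusted over the list alone; adjusted p = 0.201 with an estimated correlation), led by GINS2 (2.12) and CCNE2 (1.33). Of 28 mitotic G2/M genes 15 fell and 2 rose (17 and 2 adjusted over the list alone; adjusted p = 0.522 with an estimated correlation), such as ECT2 (-0.67) and TOP2A (-0.63). Luminal markers fell in 12 of 22 and rose in 3 (13 and 3 adjusted over the list alone; adjusted p = 0.077 with an estimated correlation), with KRT18 at -0.80. Of 24 oestrogen receptor targets 11 fell and 4 rose (12 and 5 adjusted over the list alone; adjusted p = 0.263 with an estimated correlation), with MYB at -2.37 and GREB1 at 1.94.

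Stress genes of the ATF4 and unfolded-protein list rose in 16 of 22 and fell in 1 (16 and 1 adjusted over the list alone; adjusted p = 0.284 with an estimated correlation), for example DDIT4 (1.33) and CHAC1 (1.47). Cholesterol synthesis genes rose in 15 of 22 and fell in 1 (15 and 2 adjusted over the list alone; adjusted p = 0.284 with an estimated correlation), including SQLE (0.59). Fatty acid genes rose in 7 of 19 and fell in 3 (7 and 3 adjusted over the list alone; adjusted p = 0.077 with an estimated correlation), including ACSL1 (1.49). Immediate-early genes rose in 15 of 27 and fell in 4 (15 and 4 adjusted over the list alone; adjusted p = 0.077 with an estimated correlation). TGF-beta and BMP response genes fell in 8 of 17 and rose in 2 (8 and 3 adjusted over the list alone; adjusted p = 0.077 with an estimated correlation), including BMP4 (-0.79). Interferon-stimulated genes were called lower in 15 of 31 and higher in 1 (15 and 2 adjusted over the list alone; adjusted p = 0.888 with an estimated correlation), but this rested on si-control 0 h replicate 1. The list median was 106 CPM in that library, 56.7 in replicate 2 and 54.4 and 51.7 at 6 h, and without that library 6 were lower and 9 higher. The lists of NF-kB targets (3 higher and 5 lower of 14), basal markers (6 and 2 of 16), p53 targets (4 and 5 of 20), SWI/SNF subunits (5 and 5 of 23), HP1 proteins and co-repressors (7 and 4 of 18), linker histones (1 and 1 of 6) and core histones (0 and 2 of 9) did not pass. Adjusted over the list alone, these counts were 3 and 5, 8 and 3, 4 and 5, 7 and 5, 7 and 5, 1 and 1, and 0 and 2, in the same order. Markers of other cell types gave 2 higher and 3 lower of 13 mesenchymal genes while the leukocyte (7 genes) and endothelial (3 genes) lists had camera adjusted p of 0.871 and 0.884. Over all 18806 genes, 3665 rose and 3405 fell, of which 1014 and 784 by at least 2-fold. With the 4 siRNA conditions averaged, 3931 genes rose and 4147 fell of 16421.

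**Figure D2:**
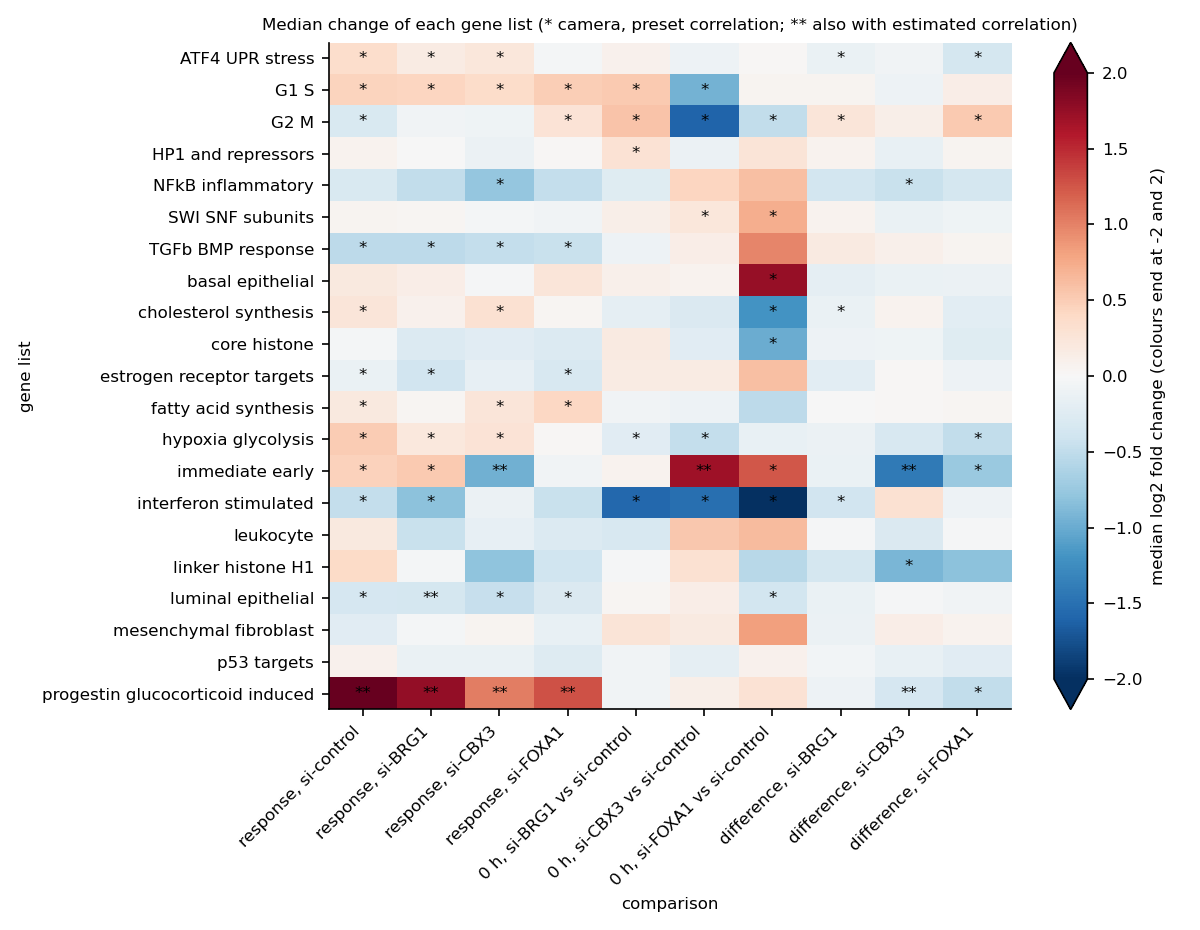
Median log2 fold change of each gene list with at least 6 measured genes (vertical axis) in 10 comparisons (horizontal axis); 1 star marks camera calls with the preset correlation and 2 stars those kept with an estimated correlation. Progestin-induced genes carry 2 stars in each of the 4 hormone responses, and immediate-early genes in si-CBX3 before hormone, in its response and in the difference; the other 2 such calls are progestin-induced genes in the si-CBX3 difference and luminal markers in the si-BRG1 response.

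Cells without siRNA, with 1 library per time and no test, moved in the same direction for 5209 of 6599 genes called in si-control (78.9%, 95% interval 77.9 to 79.9), 88.0% of induced and 69.1% of repressed genes. The log2 ratios without siRNA were not centred. Their median was 0.0396 over all 17398 genes and 0.164 over the 9322 with a mean log-CPM of 3 or more. Such an upward shift can raise the share of induced genes and lower that of repressed genes. The shares thus do not tell whether repression was reproduced less well than induction. FKBP5 was at 3.32 RPKM before and 34.6 RPKM after hormone, and AMIGO2 at 5.93 and 0.104 RPKM. The progestin-induced list had a median log2 ratio of 1.29, above all 10000 random lists. Immediate-early and ATF4 stress genes, mostly raised in si-control, did not stand out, with medians of 0.01 and 0.20 at percentiles 19.9 and 54.35 of random lists. Across genes, which are not independent replicates, Pearson's r between these ratios and the si-control response was 0.33 and Spearman's rho 0.426 (17398 genes); r was 0.581 for the 9322 genes with a mean log-CPM of 3 or more.

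Before hormone, cell cycle genes were higher and interferon-stimulated genes lower in si-BRG1 than in si-control. Of 28 G2/M genes 27 were higher (28 adjusted over the list alone), such as TOP2A (0.76) and BIRC5 (0.73), and of 26 G1/S genes 23 were higher (23 adjusted over the list alone), such as MCM10 (0.98) and E2F1 (0.84), and both lists had adjusted p = 0.169 with an estimated correlation. Interferon-stimulated genes were lower in 30 of 31 (30 adjusted over the list alone; median -1.57), including IFIT3 (-2.65, SE 0.26), IFI27 (-2.56), IFIT1 (-2.28), ISG15 (-2.14) and IFITM1 (-2.13), with adjusted p = 0.218 with an estimated correlation. This list was also lower than in si-control in si-CBX3 and si-FOXA1. In the 0 h library without siRNA, quantified in another way, it lay below si-control (median log2 ratio -4.19) and below si-BRG1 (-2.41). A level particular to the si-control libraries may thus account for part of these falls. The 2 si-control 0 h libraries differed in interferon-stimulated genes, with IFIT1 at 739 and 315 CPM. Without replicate 1 the calls of TRIM22 and of the named interferon-stimulated genes were smaller, between -2.23 for TRIM22 and -1.27 for IFITM1. Lower levels were also called for the antiviral gene TRIM22 (-2.83), FMOD (-2.23) and 10 of 21 glycolysis genes (11 adjusted over the list alone; adjusted p = 0.169 with an estimated correlation), led by LDHA (-0.69). OSBPL5, a lipid transfer gene, was 4.05-fold higher (2.02, SE 0.09), and LIN28A (1.99), ZNF664 (1.83), CENPE (1.67), ZNF589 (1.65), ZNF702P (1.65), SLC23A1 (1.57) and ZNF37BP (1.55) were the next largest rises. Co-repressor genes were higher in 8 of 18 and lower in 1 (10 and 2 adjusted over the list alone; adjusted p = 0.218 with an estimated correlation), including HDAC1 (0.73). In all, 2841 genes were higher and 2511 lower, but 2490 and 3065 with DESeq2's size factors and 2455 and 3091 with DESeq2, so which direction prevails depends on the scaling. The total of 5352 fell to 3246 without si-BRG1 0 h replicate 1, to 3289 without replicate 2 and to 3533 without si-control 0 h replicate 2.

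In si-CBX3 before hormone, immediate-early genes were mostly higher and cell cycle genes mostly lower. Of 27 immediate-early genes, first targets of growth factor signalling, 24 were higher and 1 lower (25 and 1 adjusted over the list alone), with FOS at 5.32 (SE 0.18), CCN1 at 2.79 (SE 0.09), JUN at 2.29 and PHLDA1 at 1.97, and adjusted p = 0.00441 with an estimated correlation. G2/M genes were lower in 25 of 28 (25 adjusted over the list alone; median -1.61; adjusted p = 0.133 with an estimated correlation), such as CDC20 (-2.27) and CCNB1 (-1.77). G1/S genes were lower in 23 of 26 with 1 higher (24 and 1 adjusted over the list alone; adjusted p = 0.159 with an estimated correlation), such as RRM2 (-1.74) and MCM2 (-1.24). Glycolysis genes were lower in 15 of 21 (16 adjusted over the list alone; adjusted p = 0.133 with an estimated correlation), and interferon-stimulated genes were lower in 26 of 31 with 1 higher (26 and 1 adjusted over the list alone; adjusted p = 0.448 with an estimated correlation). SWI/SNF subunits were higher in 13 of 23 and lower in 2 (14 and 2 adjusted over the list alone; adjusted p = 0.165 with an estimated correlation). ANKRD35 (3.65), OSBPL5 (3.05), the arginine deiminase gene PADI2 (2.97), RRBP1 (2.82) and LTBP2 (2.76) were among the largest rises; BCAN, called at 3.89 (2.82 and 8.28 without si-control 0 h replicate 1 and 2), was at 0.636 CPM against 0.0427. After CBX3 itself, the largest falls were ENSG00000265150 (-5.04), ENSG00000258486 (-4.13), IFI27 (-3.28), ENTPD3 (-3.20), GBP1 (-2.73), CCL28 (-2.73) and MTND3P25 (-3.23), a mitochondrial pseudogene whose reads cannot be told from those of its near-identical copies. IFI27 was at -2.52 without si-control 0 h replicate 1, and MTND3P25 at -4.03 without si-CBX3 0 h replicate 1. ENSG00000265150 and ENSG00000258486 were at 225000 and 260000 RPKM in the 0 h library without siRNA. Their mean log-CPM in the siRNA libraries was 3.98 and 3.68. The scales differ, but so wide a gap between sets of libraries limits what their falls say about CBX3, and its cause was not tested. In all, 5283 genes were higher and 4894 lower, but 4863 and 5320 with DESeq2's size factors and 4558 and 5104 with DESeq2.

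In si-FOXA1 before hormone, luminal and cholesterol synthesis genes were mostly lower and basal markers mostly higher, none past camera with an estimated correlation. Luminal genes were lower in 15 of 22 and higher in 6 (15 and 6 adjusted over the list alone; adjusted p = 0.217 with an estimated correlation), with AGR2 at -4.62 (SE 0.08) and ESR1 at -0.60, against a rise of TFAP2B (4.70). Basal genes were higher in 12 of 16 and lower in 1 (12 and 1 adjusted over the list alone; median 1.74; adjusted p = 0.0834 with an estimated correlation), including TRIM29 (2.79), CDH3 (1.91), ITGA6 (1.85) and EGFR (1.55). Cholesterol synthesis genes were lower in 20 of 22 and higher in 1 (20 and 1 adjusted over the list alone; median -1.20; adjusted p = 0.112 with an estimated correlation), such as SC5D (-2.59), EBP (-1.90) and IDI1 (-1.86), enzymes of the pathway. Immediate-early genes were higher in 24 of 27 and lower in 2 (24 and 2 adjusted over the list alone; adjusted p = 0.0834 with an estimated correlation), with MYC at 2.88 and CCN2 at 5.84. SWI/SNF subunits were higher in 17 of 23 and lower in 3 (17 and 3 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation). Core histones were lower in 6 of 9 and higher in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.271 with an estimated correlation). G2/M genes were lower in 18 of 28 and higher in 5 (18 and 5 adjusted over the list alone; adjusted p = 0.529 with an estimated correlation). Interferon-stimulated genes were lower in 29 of 31 (29 adjusted over the list alone; median -3.05; adjusted p = 0.417 with an estimated correlation), including ISG15 (-5.77, and -4.99 without si-control 0 h replicate 1).

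Single genes moved by large amounts in si-FOXA1. BCAN, a brain proteoglycan gene, was at 34.3 ± 1.16 CPM (SD, n = 2) against 0.0427 ± 0.0604 in si-control. The chemokine gene CCL22 rose 66.9-fold (6.06, SE 0.13), and ADGRA2 (4.58), NEDD9 (4.58), FAT2 (4.52), RNF207 (4.38) and NTN4 (4.30) were among the other large rises, ADGRA2 being at 5.34 without si-control 0 h replicate 1. CRYM fell 105-fold (-6.72, SE 0.24; -6.08 and -7.80 without si-FOXA1 0 h replicate 1 and 2), with SRARP (-5.95), GNMT (-5.89), MATN3 (-5.88), ENTPD3 (-5.78), TGM3 (-5.72) and FMOD (-5.65) next. H1-2, which encodes H1.2, was lower in si-FOXA1 (-1.63, SE 0.11), si-CBX3 (-0.86, SE 0.11) and si-BRG1 (-0.37, SE 0.11), the last not called without some single libraries (adjusted p up to 0.0813). In all, 7526 genes were higher and 6302 lower in si-FOXA1. The si-CBX3 and si-FOXA1 libraries were counted in another run than si-control, so for changes that both show, a batch of that run and the siRNAs cannot be told apart. A batch common to both does not account for where they differ, as in basal markers (median 0.08 in si-CBX3 and 1.74 in si-FOXA1) or cholesterol synthesis genes (-0.29 and -1.20).

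**Figure D3:**
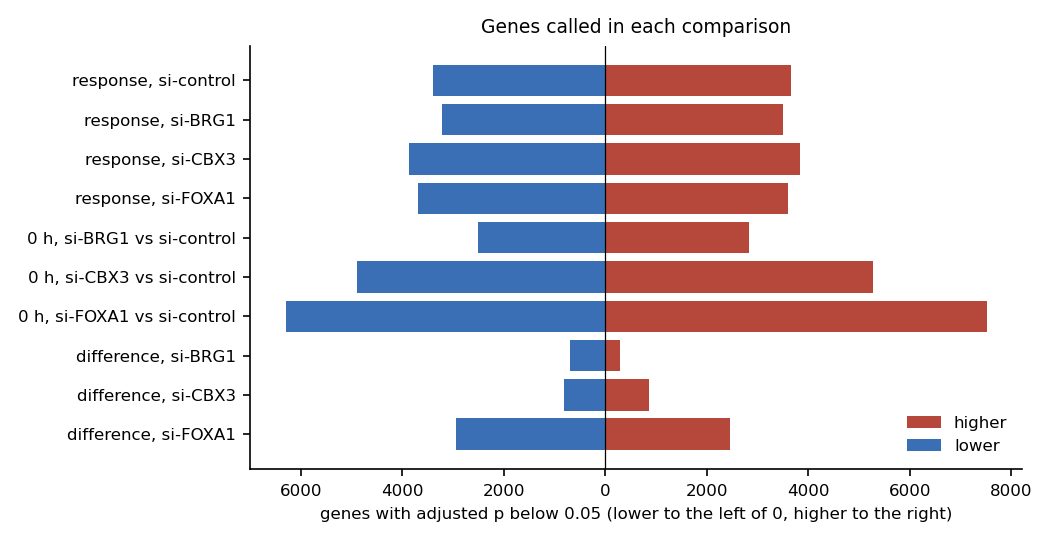
Number of genes with an adjusted p below 0.05 (horizontal axis, lower to the left and higher to the right of 0) in each of 10 comparisons (vertical axis). The si-FOXA1 effect before hormone (7526 and 6302) has the longest bars, and the si-BRG1 difference of response (281 and 700) the shortest.

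The effects of the 3 knockdowns before hormone overlapped. In all 3, 1571 genes were higher and 1551 lower. The pairs shared 3794 (si-BRG1 and si-CBX3), 3986 (si-BRG1 and si-FOXA1) and 7132 calls (si-CBX3 and si-FOXA1) in the same direction; independent lists would give 798 higher and 653 lower genes, 1140 and 841, and 2110 and 1640, and simulations of unchanged groups gave 0. Those groups had 0 calls each, so their overlap of 0 is no measure of the shared si-control libraries. Across genes r was 0.568, 0.511 and 0.566 (simulated mean 0.048, 0.0453 and 0.0525) with covariances of 0.328, 0.481 and 0.781 (simulated 0.00424, 0.00405 and 0.00466). The simulated groups were drawn around the fitted si-control means, so their r and covariances are no measure of the shared libraries either. The same 2 si-control libraries at 0 h enter all 3 comparisons and were not split, so part of the excess may come from them.

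FKBP5 and PGR responded to hormone in the same direction under each siRNA. FKBP5 rose by 3.36 (SE 0.07) in si-BRG1, 2.59 (SE 0.07) in si-CBX3 and 3.06 (SE 0.07) in si-FOXA1, and PGR fell by 1.73, 1.83 and 1.36. Progestin-induced genes rose in 20, 19 and 17 of 25, with adjusted p of 0.00509, 0.0162 and 0.0291 with an estimated correlation. Immediate-early genes, of which 15 rose and 4 fell in si-control, fell in 19 of 27 and rose in 4 in si-CBX3 (19 and 4 adjusted over the list alone; median -0.96; adjusted p = 0.0204 with an estimated correlation). Luminal markers fell in 13 of 22 in si-BRG1 (15 adjusted over the list alone; adjusted p = 0.0355 with an estimated correlation). The responses held 3496 higher and 3210 lower genes in si-BRG1, 3842 and 3860 in si-CBX3 and 3600 and 3695 in si-FOXA1; the si-BRG1 total of 6706 fell to 4342 when only its own groups were fitted. Of genes induced in si-control 67.2%, 69.7% and 47.2% were called in the same direction, and of repressed genes 57.3%, 64.3% and 40.7%. Across genes, Spearman's rho with the si-control response was 0.613, 0.634 and 0.327 (Pearson's r 0.694, 0.655 and 0.494).

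**Figure D4:**
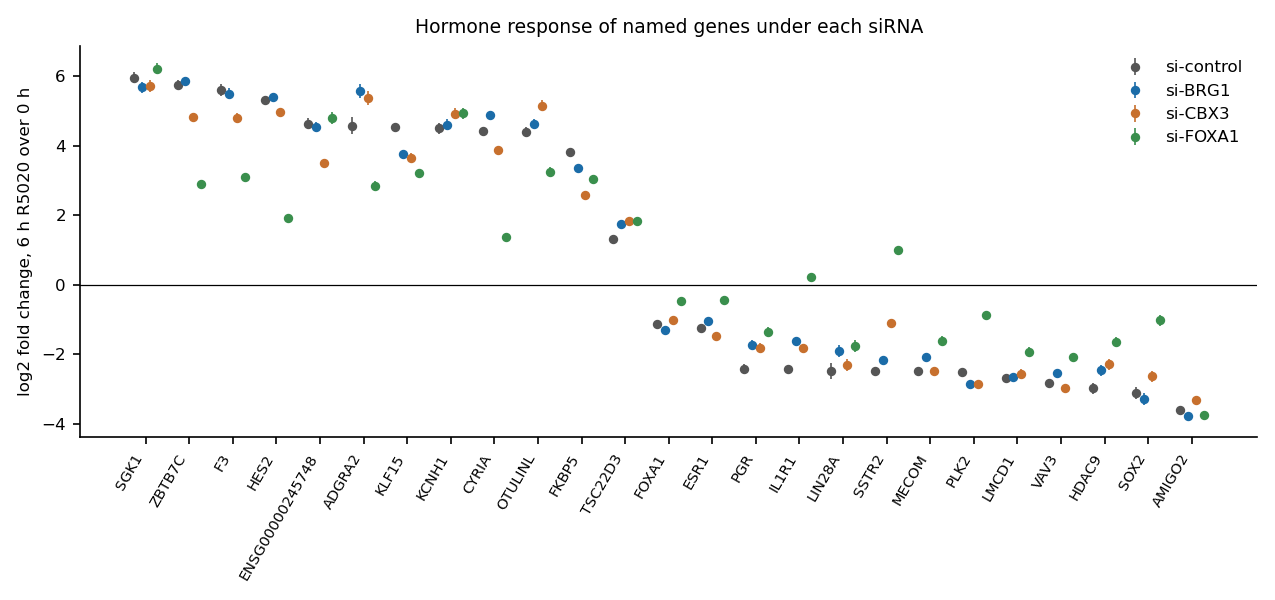
Hormone response (log2 fold change, 6 h over 0 h, vertical axis; bars are standard errors) of named genes (horizontal axis) under the 4 siRNAs, n = 2 libraries per group. HES2 and CYRIA rise less under si-FOXA1 than under si-control, and SSTR2 falls in si-control (-2.48) and rises in si-FOXA1 (0.99).

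Genes that responded to hormone in si-control responded less in si-FOXA1. The median change of response was -0.39 for 3665 induced and 0.35 for 3405 repressed genes (camera adjusted p = 0.00342 with an estimated correlation for both). It was -0.12 and 0.19 in si-BRG1 (adjusted p = 0.0253 and 0.0211 with an estimated correlation) and -0.11 and 0.12 in si-CBX3 (0.0819 and 0.0762). These classes were chosen on the si-control libraries that also enter the difference. Classes were also taken from the libraries without siRNA, as 819 induced and 233 repressed genes changed at least 2-fold there with a mean log-CPM of 3 or more. The medians stayed past the test in si-FOXA1 (-0.18 and 0.26, camera adjusted p = 0.0416 with an estimated correlation) but not in si-BRG1 (0.03 and 0.11) or si-CBX3 (-0.01 and 0.06). The nearest si-control class, genes changed at least 2-fold, had medians of -0.79 and 0.92 in si-FOXA1. With classes from the average response, the si-FOXA1 medians were -0.10 and 0.07 and missed the test with an estimated correlation (adjusted p = 0.0575 and 0.228). Among genes changed at least 2-fold in si-control, the medians were -0.14 and 0.36 in si-BRG1 (adjusted p = 0.0697 and 0.0223 with an estimated correlation), -0.28 and 0.32 in si-CBX3 (0.0216 and 0.0404) and -0.79 and 0.92 in si-FOXA1 (0.00143 for both).

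**Figure D5:**
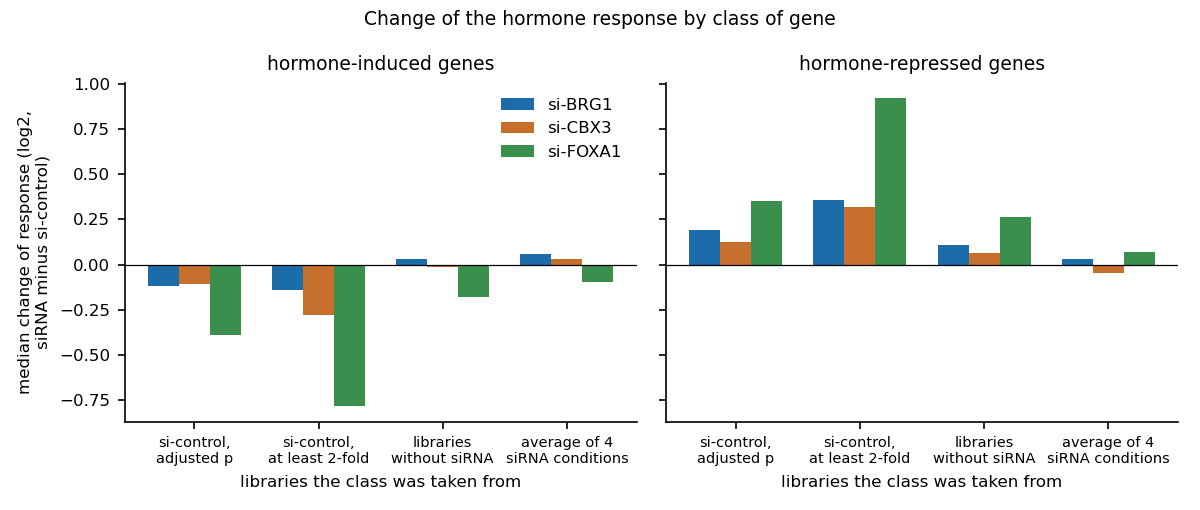
Median change of the hormone response (log2, each siRNA minus si-control, vertical axis) of induced and repressed genes, with the class defined in 4 ways (horizontal axis). Where the class comes from the average response or from the libraries without siRNA, bars of all 3 siRNAs shrink, those of si-FOXA1 keeping their sign and some of si-BRG1 and si-CBX3 turning.

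In si-BRG1 CYP1B1, an oestrogen-metabolising enzyme gene, responded higher by 1.19 (SE 0.15), as did CDK6 (1.21), DNAJB4 (1.17), MGAT4A (1.07), RAB31 (1.06), ENC1 (1.06), ACOT6 (0.96) and TRIM22 (1.54, and 0.95 without si-control 0 h replicate 1). BCL3 (-1.29, SE 0.17), ANGPTL4 (-1.28), VASN (-1.23) and the AP-1 gene JUNB (-1.22) responded lower, with CCDC85B (-1.89), HES4 (-1.47), MRPL38 (-1.44) and COMTD1 (-1.36). The falls of PGR and rises of FKBP5 were smaller, by 0.70 and -0.45, and the rise of TSC22D3 was larger by 0.45. Of 22 cholesterol synthesis genes 4 responded lower (4 adjusted over the list alone; adjusted p = 0.539 with an estimated correlation), and the G2/M list had a median of 0.24 (adjusted p = 0.551 with an estimated correlation) with 0 of 28 genes called by edgeR (0 adjusted over the list alone, 0 by DESeq2, and 6 higher at an unadjusted p below 0.05). Of 14 NF-kB targets 4 responded lower (5 lower and 1 higher adjusted over the list alone; adjusted p = 0.539 with an estimated correlation), including RELB (-0.69), and the list did not pass with the preset correlation either (adjusted p = 0.149). Of 22 ATF4 stress genes 3 responded lower (7 adjusted over the list alone; adjusted p = 0.576 with an estimated correlation). Of 31 interferon-stimulated genes 1 responded lower (1 adjusted over the list alone; adjusted p = 0.696 with an estimated correlation). Their median of -0.38 was -0.673 without si-control 0 h replicate 1 and -0.014 without replicate 2. Totals were 281 higher and 700 lower, but 444 and 410 without si-control 0 h replicate 1. The count of 981 ranged from 147 (without si-BRG1 0 h replicate 1) to 2840 (without si-BRG1 6 h replicate 1) with 1 library left out. It was 409 without si-BRG1 0 h replicate 2, 364 without si-control 0 h replicate 2, 531 and 179 without si-control 6 h replicate 1 and 2, and 67 with only these groups fitted. Of the 26 named calls 15, TRIM22, CCDC85B, HES4, MRPL38, COMTD1, RELB, PGR, FKBP5 and TSC22D3 among them, were lost without some library.

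Immediate-early genes responded lower to hormone in si-CBX3. Of 27, 21 were lower (25 adjusted over the list alone; median -1.42; adjusted p = 0.000108 with an estimated correlation), with FOS at -4.75 (SE 0.27), the MAP kinase phosphatase gene DUSP1 at -2.16 (SE 0.11), CCN1 at -2.06 and KLF6 at -1.53. At 6 h, a comparison added after the data were seen, 9 of the 27 were higher than in si-control and 6 lower (median 0.19, camera adjusted p = 0.415). Before hormone 24 were higher in si-CBX3 (median 1.695) and 24 in si-FOXA1 (median 1.246), which was counted with the same settings. In si-BRG1, counted as si-control was, 7 were higher and 6 lower (median 0.075). The lower response thus goes with a higher level before hormone. For that level a batch of the counting run and the siRNA cannot be told apart. CENPE (-2.45), RASD2 (-2.02), BHLHE40 (-1.88), RND3 (-1.88), JUN (-1.85) and SIK1 (-1.84) responded lower as well, the call of CENPE being lost without some library, with values of -1.70 and -4.09 without si-CBX3 6 h replicate 1 and 2. CDK6 (2.16, SE 0.18), LRR1 (1.76), GJB2 (1.68), AMD1 (1.68), MGAT4A (1.67), the prostaglandin receptor gene PTGER3 (1.66), CDK5R1 (1.61) and TCF7L1 (1.51) responded higher. Progestin-induced genes responded lower in 9 of 25 and higher in 2 (12 and 2 adjusted over the list alone; adjusted p = 0.0422 with an estimated correlation), including FKBP5 (-1.23) and ERRFI1 (-1.33). Linker histones were lower in 2 of 6 (2 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation) and NF-kB targets in 3 of 14 with 1 higher (6 and 1 adjusted over the list alone; adjusted p = 0.168 with an estimated correlation). Totals were 870 higher and 820 lower; the count of 1690 fell to 825 without si-CBX3 6 h replicate 2, and lay at 833 to 1068 without si-CBX3 0 h replicate 2 (833) or 1 (1068), si-CBX3 6 h replicate 1 (985), si-control 0 h replicate 2 (1040) or si-control 6 h replicate 2 (979).

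In si-FOXA1 SSTR2, a somatostatin receptor gene, responded higher by 3.48 (SE 0.14), and CHST1 (3.82), GASK1B (3.16), ATP13A4 (3.15), XYLT1 (3.10), the tight junction gene CLDN1 (3.03), EDARADD (2.89) and CALD1 (2.78) did too. GLUL, glutamine synthetase, responded lower by 3.24 (-3.24, SE 0.11), with FRMD3 (-3.49), HES2 (-3.41), CDC42EP3 (-3.31), NEDD9 (-3.28), SYBU (-3.20), CYRIA (-3.06) and RASD2 (-3.05). The falls of PGR (1.06), ESR1 (0.80) and FOXA1 (0.66) were smaller than in si-control. Glycolysis genes responded lower in 13 of 21 and higher in 1 (14 and 1 adjusted over the list alone; adjusted p = 0.0974 with an estimated correlation), including PFKFB3 (-1.92) and SLC2A1 (-1.52). Progestin-induced genes responded lower in 12 of 25 with 2 higher (14 and 3 adjusted over the list alone; adjusted p = 0.0974 with an estimated correlation), including STAT5A (-1.58). Immediate-early genes were lower in 11 of 27 and higher in 2 (12 and 2 adjusted over the list alone; adjusted p = 0.0974 with an estimated correlation). ATF4 stress genes were lower in 11 of 22 and higher in 1 (13 and 1 adjusted over the list alone; adjusted p = 0.565 with an estimated correlation). G2/M genes were higher in 15 of 28 (19 adjusted over the list alone; adjusted p = 0.525 with an estimated correlation), such as ECT2 (1.01). Totals were 2451 higher and 2950 lower.

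Response differences were shared between knockdowns in the same direction for 388 genes (si-BRG1 and si-CBX3; independent lists would give 13 higher and 30.5 lower), 661 (si-BRG1 and si-FOXA1; 36.6 and 110) and 825 (si-CBX3 and si-FOXA1; 113 and 129). Simulated unchanged groups had 0 calls, so their overlap of 0 is no measure of the shared libraries. Across genes the covariances were 0.347, 0.398 and 0.36 (simulated 0.00612, 0.00437 and 0.00605). The simulated covariances are no measure of the shared libraries either, since those groups were drawn around the fitted si-control means. In all 3, 96 genes were higher and 176 lower, a total of 272 that fell to 77 without si-control 6 h replicate 2, to 117 without si-control 0 h replicate 2 and to 173 without si-control 6 h replicate 1. All 3 differences share the 4 si-control libraries, and part of the excess may come from these.

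The BRG1 list held 2288 peaks before hormone and 6180 at 30 min, with 1 library each. Of the 0 min peaks 668 (29.2%, 95% interval 27.4 to 31.1) overlapped a 30 min peak. Peaks within 5 kb of a 5 prime gene end made up 20.2% at 0 min and 34.6% at 30 min. By the authors' score the highest 30 min peaks lay over the 5 prime ends of VEZF1 (chromosome 17, 56060485 to 56066988, exonic), TRPS1 (chromosome 8, 116815603 to 116822563, exonic) and MED13L (chromosome 12, 116709192 to 116716837, exonic); at 0 min they lay on chromosome 8 (116908311 to 116910849, intergenic), in an intron of CADM2 (chromosome 3, 85317169 to 85322082) and in an intron of MED13L (chromosome 12, 116700322 to 116707027). At 30 min but not at 0 min, a peak covered the 5 prime end of FKBP5 (chromosome 6, 35693131 to 35696411, exonic), and others lay near PGR (chromosome 11, 100997483 to 101000957), DUSP1 (chromosome 5, 172197113 to 172198899) and GLUL (chromosome 1, 182358588 to 182362042). CBX3 had a peak at its 5 prime end in both lists.

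Genes that responded to hormone in si-control carried 30 min BRG1 peaks more often than other genes. A peak lay within 5 kb of 515 of 3665 induced genes (14.1%; odds ratio 1.92, 95% interval 1.72 to 2.16; Fisher's exact test, two-sided, p = 2.45e-27) and 501 of 3405 repressed genes (14.7%; odds ratio 2.03; p = 6.52e-31), against 919 of 11736 others (7.83%). In the 0 min list the odds ratio was 2.18 for repressed genes (Fisher's exact test, two-sided, p = 4.57e-10) and 0.969 for induced genes (interval 0.717 to 1.31; p = 0.879). For the 30 min list pooled over 10 bins of mean log-CPM (Mantel-Haenszel), the odds ratios were 1.66 for induced and 1.88 for repressed genes. Among genes changed at least 2-fold they were 2.42 and 1.47, so which class has the higher ratio depends on the threshold. With 1 library per time, the peak lists have no replicate check, and these tests take genes as independent.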

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

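Tests chosen only after the result was seen are those of the counting runs and of si-FOXA1 material, the standard deviation left after a length trend, the values on expressed genes alone and the levels at 6 h.

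The hormone response differed from that of si-control, by a test of the difference itself, for 981 genes in si-BRG1, 1690 in si-CBX3 and 5401 in si-FOXA1. Genes called in opposite directions under the siRNA and si-control, with a called difference, numbered 93, 126 and 717. In si-CBX3 the median difference of response was -0.333 over the progestin- and glucocorticoid-induced list and -1.416 over the immediate-early list, both past camera with an estimated correlation. The immediate-early genes were higher in si-CBX3 before hormone (24 of 27), and at 6 h 9 were higher and 6 lower. They were also higher before hormone in si-FOXA1 (24 of 27), counted with the same settings, so a batch of that run cannot be told apart from the siRNAs. Other splits of the 16 libraries were tried for the average response. Of 100 splits, 1 gave as many genes, the real one with 8078. The highest other split gave 5383 and shares 14 of 16 labels with it, and 97 of the 100 gave 0 genes. A split that mixes 0 h and 6 h libraries puts the hormone effect into the spread, so such splits were bound to give few genes. They do not measure chance, and no conclusion on it is drawn from them.

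Interferon-stimulated genes were higher in si-control before hormone than in each of the other siRNA groups. The counting runs are argued against, since si-BRG1, counted as si-control was, had a median of -1.572 over the list. A single deviating si-control library is argued against as well: without si-control 0 h replicate 1 the medians were -1.152 in si-BRG1, -0.94 in si-CBX3 and -2.64 in si-FOXA1. A level particular to the si-control libraries may account for part of the pattern. The 0 h library without siRNA had a median log2 ratio of -4.19 to si-control, and -2.41, -2.43 and -0.41 to si-BRG1, si-CBX3 and si-FOXA1. It is 1 library quantified in another way. These ratios are relative to all genes and use a pseudocount of 0.1 RPKM. Genes such as IFIT1 (0.475 RPKM) and IFIT3 (0.221 RPKM) were low without siRNA, so the size of the ratios depends in part on that choice. An effect of the knockdowns themselves stays open, untested.

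The 2 si-BRG1 6 h libraries differed more than those of any other group, with a chi-square per degree of freedom of 57.1 against 28.0 for si-control 0 h and 22.05 for si-FOXA1 6 h. A weaker knockdown in replicate 2 is argued against: across genes the difference correlated with the si-BRG1 effect before hormone at r = 0.152, where that explanation needs a negative value, although SMARCA4 was at 2.26 and 5.66 CPM. Transcript length followed the difference with a rho of 0.197, between the bounds set beforehand, and removing its trend left the standard deviation at 0.482 from 0.488, above the 0.426 of the next group, which argues against length as the whole cause; over 12278 expressed genes rho was 0.424 and the standard deviation 0.271 from 0.294, against 0.207. Material of a si-FOXA1 6 h library in replicate 2 cannot be told apart from no such material. The median excess of 24 markers was 1.43% of the si-FOXA1 level, with a standard error of 0.707 from resampling the markers. Across genes the difference correlated with the si-FOXA1 effect before hormone at r = 0.291, against 0.157 for the replicates of the next group, si-FOXA1 6 h. That r goes with such material but does not measure its share. The markers disagreed: KRT16 and BCAN, the most abundant, had an excess of -0.263% and -0.445% (counting error 0.278 and 0.187), and NES and TNNI2, the next, 1.16% and 3.42% (0.677 and 0.695). A rule on the 2 most abundant alone, which would have excluded a share of 1%, was tried once their values were known and dropped because the next 2 point the other way. A biological explanation was not tested.

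Hormone-responsive genes of si-control responded less under each siRNA by camera with the preset correlation, and with an estimated one not in si-CBX3. Among genes changed at least 2-fold in si-control, si-CBX3 passed with an estimated correlation (medians -0.28 and 0.317; adjusted p = 0.0216 and 0.0404) and induced genes in si-BRG1 did not (-0.139; 0.0697). Choosing the genes on the si-control libraries is argued against as the whole cause in si-FOXA1: with the class taken from the libraries without siRNA, the median change of repressed genes was 0.263 (standard error 0.0615). In si-CBX3 that choice may account for the pattern, with a median of 0.062 (0.022), and in si-BRG1 it cannot be told apart from an effect of the knockdown, with a median of 0.106 (0.021) near the bound of 0.1. With the class from the average response, the si-FOXA1 medians were smaller, at -0.096 over induced and 0.072 over repressed genes. They kept their sign but missed camera with an estimated correlation (adjusted p = 0.0575 and 0.228). What is said of this choice in si-FOXA1 thus rests on the class from the libraries without siRNA. The counting run is argued against as the whole cause in si-FOXA1. Against si-CBX3, counted with the same settings, the response was smaller by a median of 0.218 (standard error 0.00969) over repressed and -0.263 (0.00766) over induced genes. Camera with an estimated correlation gave adjusted p = 0.0109 and 0.00806. The standard errors of medians in this paragraph come from resampling genes as if independent, and leave out the spread between libraries. An effect of the FOXA1 knockdown stays open.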

How the results depend on the processing

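Tests chosen only after the data were seen are the 5 prime ends of all transcripts, the exclusion of 2 libraries together, the interferon-stimulated list of the si-control response without each library, and every alternative for the genes shared by all 3 differences of response. Where a value changed, the cause was not tested unless a cause is named.

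At an absolute log2 fold change of at least 1, which by construction passes fewer genes, the responses held 1798 genes in si-control, 1800 in si-BRG1, 2252 in si-CBX3 and 1759 in si-FOXA1; the siRNA effects before hormone 644, 2913 and 6712; the differences of response 113, 296 and 1303; and the average response 1275. With only the groups compared, which leaves fewer samples for the spread, the si-BRG1 response held 4342 genes and its difference 67. DESeq2 gave 1544 for that difference and 413 for the genes shared by all 3 differences. Without si-BRG1 6 h replicate 2 and si-control 0 h replicate 1 together, the difference held 1822 genes in si-BRG1 and 3341 in si-CBX3.

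Without each library in turn, where the lone sample is assumed to vary like the other groups, the si-BRG1 effect before hormone ranged from 3246 to 4665 genes, the difference of response from 147 to 2840 in si-BRG1 and from 825 to 2076 in si-CBX3, and the genes shared by all 3 differences from 77 to 331. The lowest and highest were without si-BRG1 0 h replicate 1 and si-control 0 h replicate 1, si-BRG1 0 h replicate 1 and si-BRG1 6 h replicate 1, si-CBX3 6 h replicate 2 and si-control 0 h replicate 1, and si-control 6 h replicate 2 and si-control 0 h replicate 1.

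With the class from the average response the median change of induced genes was 0.061 in si-BRG1 and 0.033 in si-CBX3, and of repressed genes 0.028 and -0.046. With the class from the libraries without siRNA these were 0.031 and -0.013, and 0.106 and 0.062. The si-FOXA1 medians kept their direction and call under every alternative tried with the preset correlation, at -0.10 and 0.07 with the class from the average response, where they lost the call with an estimated correlation (adjusted p = 0.0575 and 0.228). With genes changed at least 2-fold in si-control the si-CBX3 medians, -0.28 and 0.317, passed with an estimated correlation, which they did not in the larger class, and the induced median in si-BRG1, -0.139, missed it. Pearson's r of 0.33 between the libraries without siRNA and si-control was 0.424 and 0.268 with a pseudocount of 0.1 and 5, and 0.581 for genes with a mean log-CPM of 3 or more. The share of 0 min peaks that overlapped a 30 min peak was 21.5% when 0.5 of both peaks had to overlap and 31.95% with peaks widened by 500 bp. The odds ratio of a peak at induced genes was 0.969 in the 0 min list. Of the 70 list calls, 9 passed with an estimated correlation.

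Of named genes, 338 of 342 values kept direction and call with DESeq2's size factors, 334 of 339 with DESeq2, 338 of 342 with the replicate block and 1708 of 1820 with a library left out, where 89 lost the call, 10 gained one and 13 turned. The values that turned were not called in either fit. Before hormone, FOXA1 in si-BRG1 was -0.017 and PGR in si-FOXA1 -0.011 with DESeq2's size factors and with DESeq2. With each library left out, the si-control response ranged from -0.192 to 0.033 for H1-2 and from -0.049 to 0.111 for CBX3. The si-BRG1 response ranged from -0.182 to 0.238 for H1-2 and from -1.269 to 0.054 for SMARCA4, the ends being without si-BRG1 6 h replicate 1 or 2. H1-2 at 0.238 and SMARCA4 at -1.269, both without replicate 2, were called. Before hormone FOXA1 ranged from -0.036 to 0.053 in si-BRG1 and PGR from -0.162 to 0.13 in si-FOXA1. The difference in si-BRG1 ranged from -0.12 to 0.301 for H1-2, -0.022 to 0.191 for CBX3 and -1.079 to 0.243 for SMARCA4, the lowest of SMARCA4 being called, without si-BRG1 6 h replicate 2. In si-FOXA1 it ranged from -0.205 to 0.02 for H1-2, -0.036 to 0.177 for CBX3 and -0.196 to 0.005 for SMARCA4. The interferon-stimulated list of the si-control response had a median of 0.05 without si-control 0 h replicate 1, against -0.48 with all libraries.

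With the replicate block, the differences of response held 747, 1495 and 5132 genes and the si-control response 6865. Among 28 pairs of groups the replicate differences correlated across genes at -0.0587 to 0.117, so the numbers were not read as pairing the samples.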

Other observations

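The levels at 6 h, the peak comparison of induced genes and the shares of called changes are tests chosen only after the data were seen. H1-2, the H1.2 gene, was at 148 RPKM before and 87.7 RPKM after hormone in the 2 libraries without siRNA (no test), and the linker histone list had a median log2 ratio of -0.62 there, below all 10000 random lists; in si-control the H1-2 response was -0.06 (adjusted p = 0.691). The libraries without siRNA are 1 per time and were quantified in another way. Some transcripts lie far apart between the sets, such as ENSG00000265150 (225000 RPKM at 0 h without siRNA, mean log-CPM 3.98 in the siRNA libraries). The H1-2 values of the sets are thus not a like comparison, and the cause of their difference was not tested. Of 1750 induced genes with a smaller response in si-FOXA1, 1140 were lower than in si-control at 6 h and 322 higher, and before hormone 827 were higher and 519 lower. Of the 408 in si-CBX3, 176 were lower and 89 higher at 6 h, and before hormone 275 were higher and 39 lower. Of the 426 in si-BRG1, 323 were lower and 8 higher at 6 h, and before hormone 150 were higher and 25 lower. Of repressed genes with a smaller response, 780 of 1297 in si-FOXA1 were higher at 6 h and 264 lower. These counts were 147 and 57 of 319 in si-CBX3, and 79 and 7 of 133 in si-BRG1. All these genes were chosen on the difference of response itself. For induced genes that choice sets the 6 h contrast with si-control below the contrast before hormone, and for repressed genes above it. The prevailing directions were thus largely fixed by the choice and are no evidence of an effect. The counts show only at which time the levels differed.

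It was tested whether hormone-repressed genes with a 30 min BRG1 peak within 5 kb lose more of their response in si-BRG1. The difference was smaller than the 0.1 set beforehand: the median change was 0.182 for 501 genes with a peak and 0.197 for 2904 without, a difference of -0.015 (permutation test, two-sided, p = 0.266, adjusted p = 0.397 over 6 comparisons). Induced genes with a peak had a smaller median loss of response than those without under each siRNA. The class was chosen on the si-control libraries that also enter the difference, and genes with and without a peak were not matched on expression. Unequal selection can give such a contrast, so it cannot be read as an effect of the peak. The permutations take genes as independent. The medians were -0.003 against -0.135 in si-BRG1 and -0.266 against -0.403 in si-FOXA1 (permutation p = 1e-05 for both, the smallest that these permutations can give, adjusted p = 3e-05), and -0.061 against -0.118 in si-CBX3 (permutation p = 0.00173, adjusted p = 0.00346). Shares of called changes, in either direction, were compared as well (Fisher's exact test, two-sided, adjusted over 6 comparisons). With and without a peak they were 24.47% and 17.27% of induced (adjusted p = 0.000336) and 19.36% and 12.78% of repressed genes in si-CBX3 (adjusted p = 0.000336), and 50.9% and 40.74% of repressed genes in si-FOXA1 (adjusted p = 0.000148). They did not pass for induced genes in si-FOXA1 (53.98% and 55.24%; adjusted p = 0.6), nor in si-BRG1 for induced (12.43% and 14.32%; adjusted p = 0.411) or repressed genes (5.99% and 5.27%; adjusted p = 0.6).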
